A study of Mus musculus with 4 samples.

How the data were processed

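The series holds 4 samples of purified hematopoietic stem cells (HSC) from mouse bone marrow, 2 labelled young and 2 labelled old, all from mice carrying Gfp-Lc3, a green fluorescent protein fused to the autophagosome protein LC3. Per the labels' protocols, cells were profiled by droplet single-cell RNA sequencing and by plate-based SmartSeq2 with index sorting. The labels' protocols and the series' design text differ on the number of droplet samples loaded per condition. The files used here are 8 tables of the authors' own comparisons between groups of cells named c1 to c7: each of the 7 against the rest, and c1 against c2. Which assay the tables came from, how the groups were defined and which test gave the p-values are not given in the sources used here. Per the submitters' processing notes, Scanpy, GSNAP and HTSeq were used with the GRCm38.p4 genome, with no role stated for each. How doublets were treated and which cells were filtered out are not given in the sources used here.

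Each table lists 20062 genes. The column of mean expression is deposited on a log2 scale, as read from the values: 2 raised to the column summed to 10000 over genes, where a natural log gave 34992. It was the same in all 8 tables, and 8 genes held a spreadsheet error text in place of a number. The authors' deposited fold changes are log2 values limited to the range from -4 to 4, so that a value at the limit stands for at least a 16-fold difference. The reference group was settled from the values: across 989 weakly expressed genes, the c1 against c2 table was rebuilt from the c1 and c2 tables with a median absolute difference of 0.000680 (log2) when the reference was the cells outside the cluster, and of 0.129 when it was all cells. The authors' deposited adjusted p-values were the Benjamini-Hochberg adjustment of the deposited p-values over all 20062 genes, to within 4.44e-15. The number of cells, the depth per cell and the standard errors are unknown here, so fold changes are given without an interval.

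No new test between groups was made. A gene was called where the authors' adjusted p-value was under 0.05, and calls were counted per direction. The unit behind these p-values is not given. If it was the cell, a call describes these cells and not animals, since cells are not replicates. The tables hold no sample, age or GFP-LC3 level, so the planned comparison of young with old was not analysed here, nor were cells grouped by autophagy level. For 31 gene lists fixed before the data were examined, members past the threshold were counted, over all genes and adjusted over the list alone. Each list's median log2 fold change was placed among 10000 random lists of the same size matched on mean expression in 10 bins, and a list was said to stand apart at or below the 2.5th or at or above the 97.5th percentile. That percentile describes the table and is not a p-value. Genes at or above the median mean expression are called expressed genes, and their median fold change is given where it was far from 0. The ribosomal protein list was a name pattern that also took in S6 kinases (Rps6ka and Rps6kb genes), paralogs and pseudogenes such as Rpl13a-ps1. Of the mast cell and basophil list, 6 of 9 genes were in the tables, and the other lists were present in full.

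Named genes followed a rule fixed before the data were examined: in each table, the 10 highest and 10 lowest fold changes among called genes at or above the median mean expression, leaving out predicted genes; up to 4 members of each list with the largest absolute change among those called; and Map1lc3a, Map1lc3b, Sqstm1, Procr, Slamf1, Mki67 and Malat1 in any case. Ties at the limit of the fold change were broken by the smaller p-value and then the higher mean expression, which was settled after the ties were seen. Where a gene outside this rule is named, the text says so. Some genes that the rule takes are not reported here. The share of cells in each cluster was estimated from the tables, as the weights that make the cluster means average to the overall mean over genes with a log2 mean expression between -5 and -3, with a bootstrap over genes. Tested on 20000 simulated cells over 575 genes, the largest error of such a share was 0.190 percentage points. The simulated effects were centred on 0 in each cluster, unlike c6 and c7, where 11373 and 11131 of 20062 genes were at the lower limit. The error for such clusters is thus unknown, and 0.190 points is large beside the estimate of 0.353% for c7. In c1 against c2 (20054 genes), of 100 random lists of 20 genes, 1 reached the 97.5th percentile with no shift, 42 with a shift of 0.2 and 98 with a shift of 0.5 (log2).

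The alternatives tried were a stricter adjusted p, a minimum fold change, a minimum expression, the adjustment recomputed, list means in place of medians, unmatched random lists, expressed members alone and the difference of the c1 and c2 tables in place of the direct one. Leaving out X and Y genes, leaving out genes at the fold change limit and centring the fold changes were added after the data were seen. Positions are from the GENCODE M21 annotation of GRCm38, in which 19772 of the 20062 symbols were found. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.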

Results

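The series addressed which transcripts go with autophagy in HSC of old mice, at the level of single cells. The 4 samples were HSC sorted from the bone marrow of Gfp-Lc3 mice, 2 labelled young and 2 labelled old, and the deposited tables compared cells in 7 clusters, c1 to c7. Which of the samples gave cells to the tables is not given in the sources used here. Each value below is a log2 fold change of a cluster against the cells outside it, or of c1 against c2, with no replicate check, no standard error and an unknown depth. The high and low genes named for each table were taken from called genes at or above the median mean expression, and weaker genes could lie further out. From the tables, c1 was estimated to hold 40.4% of the cells (bootstrap interval over genes 40.3 to 40.6) and c2 33.6% (33.5 to 33.7). The estimates were 12.3% for c3, 10.4% for c4, 1.71% for c5, 1.06% for c6 and 0.353% for c7, and the 7 estimates summed to 99.9%. How the clusters were drawn is not given in the sources used here. If the same expression values defined them, the genes that separate a cluster were part of its definition.

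**Figure D1:**
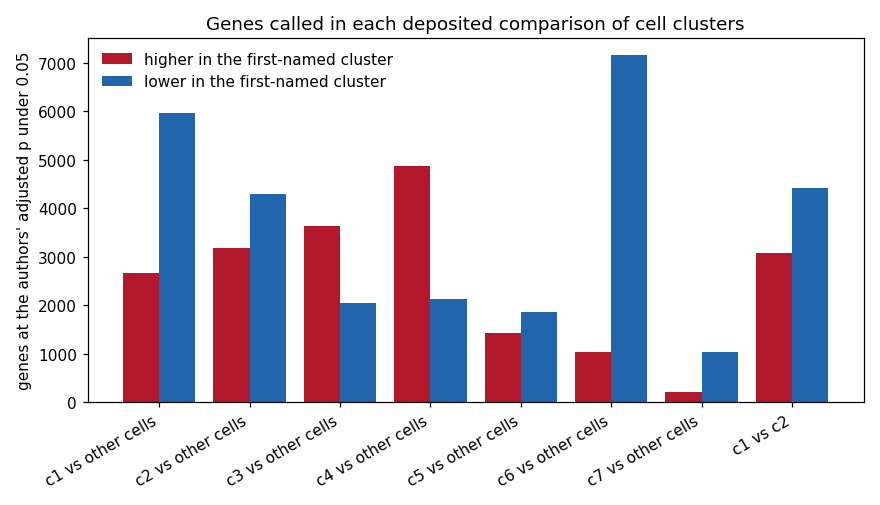
Number of genes at the authors' adjusted p under 0.05 (vertical axis) in each of the 8 deposited comparisons, with red bars for genes higher and blue bars for genes lower in the first-named cluster. Lower genes were most numerous in c6 (7155), and higher genes outnumbered lower ones in c3 (3634 against 2044) and c4 (4881 against 2124).

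Cluster c1 was marked by genes known to rise in aged HSC. In the authors' deposited table of c1 against the other cells, Cldn5, which encodes a tight junction protein, and Gpr183, an oxysterol receptor, were at the upper limit of 4. The same authors' deposited table gave 3.83 for Sbspon, 3.59 for the stress-response regulator Nupr1, 3.40 for Dnm3, a dynamin, 3.31 for Rbpjl and 3.26 for the matrix gene Matn4. Values of 3.09 for Tm4sf1, 3.04 for Bmp4, a secreted growth factor, and 3.00 for Tmem215 were also in the authors' deposited table. Of the 24 genes of the aged HSC signature, 23 were higher and none lower, with a median of 2.48 at percentile 100 of the random lists, and Osmr, a cytokine receptor subunit, stood at 3.64 in the authors' deposited table.

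Cell cycle genes were low in c1. Xist, the RNA that coats the inactive X chromosome, was at -4 in the authors' deposited table of c1, as were Cdk1, the kinase that drives mitotic entry, Mki67, Birc5, Tk1, Pbk, Spc24, Rad51ap1, Pclaf and Sgo1. All 50 genes of the G2/M list were lower in c1 (median -3.28), with Nusap1 and Ube2c at -4 in the authors' deposited table. Of the 37 S phase genes 36 were lower (median -1.71), among them Rrm2, a subunit of ribonucleotide reductase, at -3.92 in the authors' deposited table. HSC identity genes were higher for 11 of 16 and lower for 2 (median 0.31), and the authors' deposited table gave 1.07 for Procr, 0.93 for Ly6a, 0.91 for Slamf1 and 0.82 for Hoxb5. MHC class II genes were higher for 7 of 8 (median 1.10), with Cd74, the invariant chain, at 1.87 and H2-Eb1 at 1.78 in the authors' deposited table. Multipotent progenitor genes were lower for 9 of 10 and higher for 1 (median -1.35), and Cd48, a surface marker that HSC lack, stood at -4 in the authors' deposited table. Erythroid genes were lower for 9 and higher for 1 of 15, and granulocyte and monocyte genes lower for 13 and higher for 2 of 15. The higher ones were Prtn3 at 1.54 and Csf3r at 0.15 in the authors' deposited table, both named after their values were seen. Map1lc3b, which encodes an LC3 protein, was 0.40 higher in the authors' deposited table of c1, and Malat1, a nuclear RNA, was 0.45 higher, while Map1lc3a at 0.07 and Sqstm1 at 0.03 were not called. Whether reads of the Gfp-Lc3 carried by all mice were counted under Map1lc3b is unknown here, for every comparison. Core autophagy genes were lower for 10 and higher for 4 of 32 (median -0.12, percentile 57.4), and autophagy receptor genes lower for 5 of 12 and higher for none (median -0.07, percentile 74.1). In all, 8629 genes were called, 2671 higher and 5958 lower, and the median of expressed genes was -0.12. Adjusted over the list alone, the counts of the lists named here were the same, except for 10 lower erythroid genes in place of 9.

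Among the genes taken for c2, Xist was at 3.22 in the authors' deposited table of c2 against the other cells. Others in the authors' deposited table were Rgs7bp, which anchors regulators of G protein signalling, at 2.36, Nrk at 2.26, Ebi3, a cytokine subunit, at 2.09 and Socs2, a feedback inhibitor of cytokine signalling, at 2.01. The antisense RNA Tsix was at 1.97, as was Plxdc2, and Igf2bp2, an RNA-binding protein, at 1.91 in the authors' deposited table, with Mamdc2 at 1.87 and Plekhg1 at 1.79. At the lower limit of -4 in the authors' deposited table were Matn4, Sbspon, Gpr183, Zg16, the metallothionein gene Mt2 and the cycle genes Spc24, Tk1, Mki67, Birc5 and Pbk. Xist and Tsix overlap on opposite strands, and without knowledge of strand in the counting their reads cannot be told apart.

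The aged HSC signature was lower in c2 for 22 of 24 genes and higher for 1 (median -2.29, percentile 0.00). All 50 G2/M genes were lower (median -2.46), as were 36 of 37 S phase genes (median -1.20). Of the HSC identity genes 12 of 16 were higher and 1 lower (median 0.26), with the authors' deposited table giving 1.04 for the transcription factor Hlf, 0.56 for Mllt3, 0.52 for Mecom, 0.29 for Procr and -0.67 for Slamf1. Autophagy receptor genes, whose products carry cargo to the autophagosome, were higher for 10 of 12 and lower for 1 (median 0.28, percentile 99.8). They included Retreg1 at 0.68, Calcoco1 at 0.59, Ncoa4 at 0.51 and Sqstm1 at 0.43 in the authors' deposited table, where Optn was at -0.57. Of the core autophagy genes 13 of 32 were higher and 3 lower (median 0.15, percentile 99.3), led by the initiating kinase gene Ulk1 at 0.58 and by Atg14 at 0.45 in the authors' deposited table. Map1lc3a at 0.20, Map1lc3b at 0.08 and Malat1 at 0.20 were also called higher in the authors' deposited table. Interferon response genes were higher for 16 and lower for 6 of 31 (median 0.24), with the antiviral gene Mx1 at 1.92 in the authors' deposited table. Other lists stood apart too. Immediate early genes were higher for 11 and lower for 2 of 21 (median 0.25, mean -0.07). NF-kB and TNF response genes were higher for 11 and lower for 6 of 23 (median 0.20, mean -0.17). Multipotent progenitor genes were higher for 7 and lower for 3 of 10 (median 0.30), and mitochondrially encoded transcripts higher for 11 of 13 (median 0.16). MHC class II genes were lower for 8 of 8 (median -1.19), and ribosome biogenesis genes for 23 of 28 (median -0.35). Oxidative phosphorylation genes were lower for 66 and higher for 4 of 81 (median -0.28). In all, 7466 genes were called, 3181 higher and 4285 lower, or 42.6% higher. With a minimum absolute log2 fold change of 1 there were 1631, of which 17.8% were higher. Adjusted over the list alone, the counts were 23 lower genes for the aged signature, 37 for S phase, 15 higher for core autophagy, 7 lower for the interferon list and 70 for oxidative phosphorylation, with the other counts of these lists the same.

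The direct comparison of c1 with c2 set apart the pair of clusters that held most cells. Genes of the aged HSC signature were far higher in c1: 23 of 24 were higher and 1 lower, with a median of 2.83 at percentile 100. At the upper limit of 4 in the authors' deposited table of c1 against c2 were Nupr1, the metallothionein genes Mt1 and Mt2, Plscr2, Sbspon, Matn4, Gpr183, Tm4sf1, Cldn5 and Zg16. The member that was lower was Trpc6, a calcium channel gene, at -0.19 in the authors' deposited table, named after its value was seen. Xist and Rgs7bp were at -4 in the same authors' deposited table, with Tsix at -3.47, the chromatin organiser Satb1 at -3.0, Mmp8 at -2.99, Nrk at -2.97, Ebi3 at -2.87, Shisa8 at -2.83, Mtus1 at -2.78 and Cd48 at -2.60.

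On GRCm38, Nupr1 lies on chromosome 7 from 126623249 to 126630861 (minus strand), Sbspon on chromosome 1 from 15853862 to 15892722 (minus strand) and Mt1 on chromosome 8 from 94179082 to 94180327 (plus strand). Xist, a long noncoding RNA gene, lies on chromosome X from 103460366 to 103483254 (minus strand), and Satb1 on chromosome 17 from 51736187 to 51833290 (minus strand). Because Xist was at the limit, sex-linked genes were examined after the data were seen. The 4 Y-linked genes were all called higher in c1 in the authors' deposited table, at 1.03 for Eif2s3y, 0.78 for Ddx3y, 0.64 for Uty and 0.36 for Kdm5d. X-linked genes known to escape inactivation were called lower there, with -0.51 for Eif2s3x, -0.50 for Ddx3x, -0.50 for Kdm6a and -0.37 for Kdm5c in the authors' deposited table. The sex of the mice is not given in the labels used here.

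In other lists more members were called higher in c1 than in c2, and the medians of these lists stood apart except for the heat shock and glycolysis lists. MHC class II genes were higher for 8 of 8 (median 1.36, percentile 100), at 2.20 for H2-Eb1, 1.85 for H2-Aa, 1.85 for H2-Ab1 and 1.78 for Cd74 in the authors' deposited table. MHC class I genes were higher for 9 of 10 (median 0.28), with H2-D1 at 0.42 in the authors' deposited table. Megakaryocyte genes were higher for 7 and lower for 1 of 12 (median 0.52, percentile 100), and the authors' deposited table gave 2.12 for Gp1bb, 1.69 for Plek, 1.31 for the integrin gene Itga2b and -1.29 for Ppbp. Ribosome biogenesis genes were higher for 19 of 28 and lower for none (median 0.16, percentile 100), led by Odc1, the first enzyme of polyamine synthesis, at 0.51 in the authors' deposited table. Oxidative phosphorylation genes were higher for 54 and lower for 7 of 81 (median 0.13, percentile 100), and genes of the ribosomal protein pattern higher for 58 and lower for 25 of 105 (median 0.06, percentile 98.1). Unfolded protein response genes were higher for 7 and lower for 4 of 15 (median 0.17, percentile 99.5), with Sdf2l1 at 1.13, Asns at 1.08 and Xbp1 at 0.93 in the authors' deposited table. Of the heat shock genes 8 of 12 were higher and 1 lower (median 0.11, percentile 90.8), with Hspb1 at 2.30 in the authors' deposited table. Glycolysis genes were higher for 10 and lower for 3 of 20 (median 0.09, percentile 96.0), with Hk2 at 1.08 and Ldha at 0.86 in the authors' deposited table. Lysosome genes were higher for 11 and lower for 7 of 28 (median 0.08, percentile 98.7), with Cd63 at 0.68 and the cholesterol transporter gene Npc1 at -0.86 in the authors' deposited table.

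In several lists more members were called lower than higher in c1 against c2. The medians of the multipotent progenitor, G2/M and NF-kB lists stood apart from random lists, and those of the S phase, immediate early, interferon and lymphoid lists did not. Multipotent progenitor genes were lower for 10 of 10 (median -1.43, percentile 0.00), with Cd52 at -2.02 and the receptor gene Flt3 at -1.59 in the authors' deposited table. G2/M genes were lower for 27 and higher for 3 of 50 (median -0.39, percentile 0.00), with Cdk1 at -1.72, Kif2c at -1.67 and Mki67 at -0.80 in the authors' deposited table. S phase genes were lower for 19 and higher for 2 of 37 (median -0.13, percentile 13.8), led by Dtl at -1.38 in the authors' deposited table. NF-kB and TNF response genes were lower for 10 and higher for 5 of 23 (median -0.28, mean -0.03, percentile 0.57), with Cd83 at -4, Ccl3 at -1.46 and Tnfaip2 at 1.10 in the authors' deposited table. Immediate early genes were lower for 12 and higher for 2 of 21 (median -0.20, percentile 3.84), with Fosb at -1.70, Dusp1 at -1.22 and Fos at -0.85 in the authors' deposited table. Interferon response genes were lower for 12 and higher for 8 of 31 (median -0.17, percentile 5.80), with Mx1 at -2.27 and Igtp at 0.91 in the authors' deposited table. Lymphoid and B cell genes were lower for 5 of 15 and higher for none (median -0.28, mean 0.04, percentile 5.04), with Ighm at -1.77 in the authors' deposited table.

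Autophagy genes differed by small amounts between c1 and c2. Core autophagy genes were lower in c1 for 14 and higher for 5 of 32 (median -0.13, percentile 19.7). The authors' deposited table gave -0.52 for Atg16l2, -0.51 for Ambra1, -0.45 for Ulk1 and -0.44 for Atg9a, against 0.18 for Map1lc3b, and Map1lc3a at -0.09 was not called. Autophagy receptor genes were lower for 9 of 12 and higher for none (median -0.21, percentile 3.67), at -0.71 for the ferritin receptor Ncoa4, -0.60 for Retreg1, -0.37 for Calcoco1 and -0.25 for Sqstm1 in the authors' deposited table. Sqstm1 lies on chromosome 11 from 50199366 to 50210827 (minus strand) and Map1lc3b on chromosome 8 from 121590361 to 121598760 (plus strand).

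Some lists divided between c1 and c2. HSC identity genes were higher for 7 and lower for 7 of 16, with Slamf1 at 0.96, Hoxb5 at 0.55, Procr at 0.40, Hlf at -0.70 and Tek at -0.48 in the authors' deposited table; the list median of -0.05 became 0.02 when centred on the median of expressed genes. Quiescence regulators were higher for 8 and lower for 4 of 14 (median 0.18, percentile 99.8), with the cell cycle inhibitor genes Cdkn2c at 2.30 and Cdkn1a at 1.14 and the repressor Gfi1 at -1.73 in the authors' deposited table. JAK/STAT targets were higher for 4 and lower for 2 of 9 (median 0.24, mean -0.08, percentile 99.0), with Socs3 at 1.83 and Socs2 at -2.36 in the authors' deposited table. Granulocyte and monocyte genes were higher for 5 and lower for 5 of 15 (median 0.24, percentile 99.9). Erythroid genes were higher for 1 and lower for 4 of 15 (median 0.04), p53 targets higher for 3 and lower for 4 of 13 (median -0.07, mean 0.08, centred median 0.01) and mitochondrially encoded transcripts higher for 5 and lower for 7 of 13 (median -0.03, centred median 0.04). Few members were called in the lists of other cell types: 1 lower of 11 T and NK cell genes (Cd4 at -3.56 in the authors' deposited table), 1 higher of 6 mast cell and basophil genes (Cpa3, 0.78; list median 1.10, percentile 98.2), 1 lower of 10 macrophage genes (Spic, -1.42), and 1 higher and 2 lower of 10 endothelial and stromal genes.

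In all, 7505 genes were called between c1 and c2, 3082 higher and 4423 lower in c1, or 41.1% higher. With a minimum absolute log2 fold change of 1 there were 1402, of which 59.3% were higher in c1. Of these 1402, only 369 were at or above the median expression, so most were weakly expressed. Among all 5909 called genes at or above the median expression, 36.9% were higher in c1. Adjusted over the list alone, the counts for c1 against c2 were 1 higher and 11 lower autophagy receptors, 3 and 20 S phase, 5 and 11 NF-kB, 9 and 15 interferon, 13 and 7 lysosome, 6 and 5 granulocyte, 5 and 8 mitochondrially encoded, 54 and 8 oxidative phosphorylation, 60 and 25 ribosomal protein and 7 and 5 unfolded protein response genes, with the other lists the same. Across 9916 genes within the limits, the direct fold changes correlated with the difference of the c1 and c2 tables at a Pearson r of 0.996 and a Spearman rho of 0.999, both taken across genes, which are not independent replicates. These values come from the same cells, so a close match followed from the arithmetic and is no separate evidence.

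**Figure D2:**
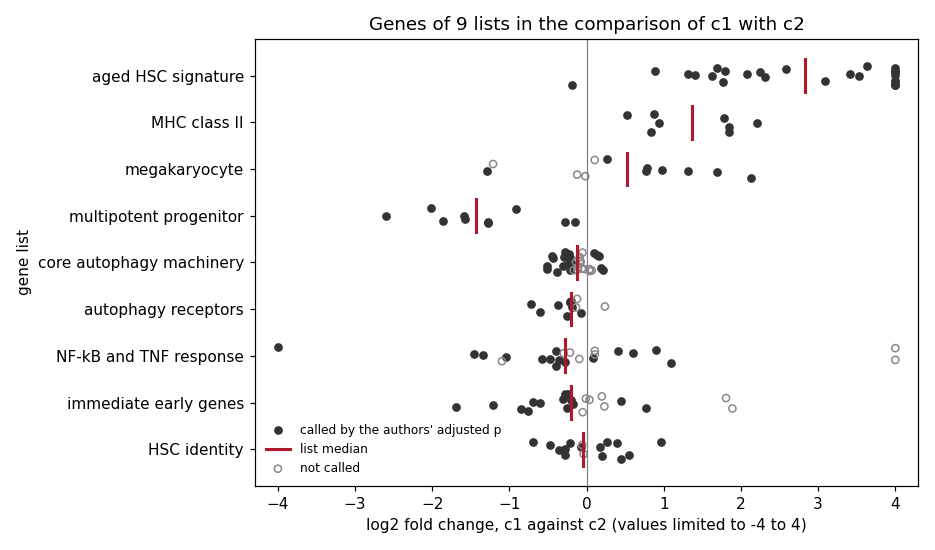
Log2 fold change of c1 against c2 (horizontal axis, limited to -4 to 4) for each gene of selected lists (vertical axis), with filled points for genes past the authors' adjusted p of 0.05, open points for the others and red bars for the list medians. The aged HSC signature has a median of 2.83 and the multipotent progenitor list one of -1.43.

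Cluster c3 was marked by genes of DNA replication and of the erythroid line. In the authors' deposited table of c3 against the other cells, the uracil glycosylase gene Ung was at the limit of 4, Car1, a carbonic anhydrase of red cells, at 3.67, Hells at 3.51, the transcription factor E2f1 at 3.48 and Uhrf1 at 3.20. The same authors' deposited table gave 3.16 for the replication licensing factor Cdt1, 3.15 for Dscc1, 3.12 for the cyclin gene Ccne2 and 3.02 for Mcm5, a subunit of the replicative helicase. All 37 S phase genes were higher (median 2.25, percentile 100), while G2/M genes divided, 17 higher and 20 lower of 50 (median -0.21), with Ube2c at -2.15 in the authors' deposited table. Erythroid genes were higher for 11 and lower for 1 of 15 (median 1.75, percentile 100), with Ermap at 4 and the master regulator Klf1 at 2.59 in the authors' deposited table. Megakaryocyte genes were higher for 7 and lower for 1 of 12 (median 0.57), with Ppbp at 1.78 in the authors' deposited table. Ribosome biogenesis genes were higher for 27 and lower for 1 of 28 (median 0.77), with Srm at 1.28 and Nop56 at 1.26 in the authors' deposited table. HSC identity genes were lower for 12 of 16 (median -0.38), the aged HSC signature for 21 of 24 (median -0.94) and core autophagy genes for 9 of 32 (median -0.15), and none of these lists had a member called higher. Procr was at -1.57, Map1lc3b at -0.52, Sqstm1 at -0.54 and Malat1 at -0.49 in the authors' deposited table. Among the genes at -4 in the authors' deposited table were genes of mature myeloid cells: Cybb, Fcgr3, Trem3, Mcemp1, Ifitm6, Lrg1, Cd177, Ly6g, Mmp8 and Fcnb. In all, 5678 genes were called, 3634 higher and 2044 lower. There were, adjusted over the list alone, 13 higher erythroid, 22 lower G2/M and 14 lower HSC identity genes, with the other counts the same. Mcm5 lies on chromosome 8 from 75109569 to 75128439 (plus strand).

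Cluster c4 was marked by genes of mitosis. At the upper limit of 4 in the authors' deposited table of c4 against the other cells were the histone genes Hist1h2ap and Hist1h2ae, the topoisomerase gene Top2a, Mki67, Birc5, Cenpf, Nusap1, Cdk1, Prc1 and Spc24. All 50 G2/M genes were higher, with a median at the limit, and 35 of 37 S phase genes were higher and 1 lower (median 1.70). Megakaryocyte genes were higher for 9 of 12 and lower for none (median 0.79), with Gp1bb at 2.75 and Itga2b at 1.24 in the authors' deposited table. Erythroid genes were higher for 5 and lower for 1 of 15, with the transcription factors Gata1 at 3.11 and Klf1 at 1.37 in the authors' deposited table, while the list median was -0.11. Mast cell and basophil genes were higher for 2 and lower for 1 of 6 (median -0.37). They were Fcer1a at 3.32, Cpa3 at 1.85 and Hdc at -4 in the authors' deposited table. Oxidative phosphorylation genes were higher for 72 and lower for 2 of 81 (median 0.51), against a median of 0.19 for expressed genes in this table. Genes of HSC identity were lower for 10 and higher for 2 of 16 (median -0.42), with Procr at -2.49 and Ly6a at -1.88 in the authors' deposited table. MHC class II genes were lower for 7 of 8 (median -1.0), with Cd74 at -2.14 in the authors' deposited table, and the aged HSC signature for 18 of 24 (median -0.95). Map1lc3a at -0.53, Map1lc3b at -0.51, Sqstm1 at -0.52 and Malat1 at -0.67 were lower in the authors' deposited table. Among the genes at -4 in the authors' deposited table were Slfn5, Cldn5, Tmem150a and the myeloid genes Trem3, Cybb, Mcemp1, Chil1, Cd177, Lrg1 and Cebpe. In all, 7005 genes were called, 4881 higher and 2124 lower. There were, adjusted over the list alone, 36 higher S phase, 74 higher oxidative phosphorylation, 11 lower HSC identity, 8 lower MHC class II and 20 lower aged signature genes, with the other counts the same. Mki67 lies on chromosome 7 from 135689784 to 135716361 (minus strand). Between c3 and c4, 2674 genes were higher in both and 1077 lower in both, where independent lists would share 884 and 216; the tables share cells, so part of the excess may come from that.

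Cluster c5 was marked by genes of granulocytes and monocytes. At the upper limit of 4 in the authors' deposited table of c5 against the other cells were Cd52, Tyrobp, Hp, Clec12a, Ly6c2, Igsf6, Ncf1 and Ncf4 (subunits of the phagocyte oxidase), Anxa3 and Fcgr3. Granulocyte and monocyte genes were higher for 14 of 15 and lower for none, with a median at the limit and Mpo, Elane, Ctsg and Ms4a3 at 4 in the authors' deposited table. G2/M genes were higher for 41 of 50 (median 1.51), with Mki67 at 1.87 in the authors' deposited table, and S phase genes for 8, with 2 lower, of 37 (median 0.23). Lysosome genes were higher for 13 and lower for 4 of 28 (median 0.47), with Neu1 at 1.51 in the authors' deposited table. Markers of other cell types moved with them: 4 of 10 macrophage genes and 3 of 11 T and NK cell genes were higher. Adgre1, Cd3d and Ighm, an immunoglobulin heavy chain, were at 4 in the authors' deposited table. List members had no minimum expression, and Adgre1 was weak, with a log2 mean expression of -8.15 against a median of -4.29 over genes. How doublets were treated is not given in the sources used here. Genes of HSC identity were lower for 15 of 16 (median -1.75), with Hlf at -2.32 and Procr at -1.66 in the authors' deposited table. Low values in the authors' deposited table were those of Shisa8 and Rgs7bp at -4, Nrk at -3.84, Rnf180 at -3.68, the sialomucin gene Emcn at -3.30, Mindy4 at -3.29, Nsg1 at -3.23, Fam181b at -3.19, Fscn1 at -3.12 and Plxdc2 at -3.07. In all, 3304 genes were called, 1439 higher and 1865 lower, and the median of expressed genes was -0.24. There were, adjusted over the list alone, 43 higher G2/M, 12 higher S phase, 14 higher lysosome, 8 higher T and NK cell and 16 lower HSC identity genes, with the other counts the same. Elane lies on chromosome 10 from 79886247 to 79888215 (plus strand).

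Cluster c6 was marked by genes of the granulocyte and monocyte list, on a background of lower values for most genes. At the upper limit of 4 in the authors' deposited table of c6 against the other cells were Pglyrp1, Hp, Wfdc21, Cd52, the calprotectin genes S100a8 and S100a9, the lysozyme gene Lyz2, Fcer1g, Lcn2, an iron-chelating granule protein, and Tyrobp. Granulocyte and monocyte genes were higher for 9 and lower for 1 of 15 (median 3.38, centred 5.62), with Cebpe and Ly6c2 at 4 and Prtn3 at -4 in the authors' deposited table. The median of expressed genes was -2.24, and list medians are given as deposited and, where stated, centred on it. Genes of the ribosomal protein pattern were lower for 91 and higher for 2 of 105 (median -3.86, centred -1.62, percentile 0.00). Ribosome biogenesis genes were lower for 28 of 28 (median at the limit, so centred at -1.76 or lower, percentile 0.02), and mitochondrially encoded transcripts for 13 of 13 (median -3.88, centred -1.64, percentile 0.92). At -4 in the authors' deposited table were Npm1, Rpl3, Rpl36a, Rpl14, Rpl22l1, Rpl10a, Rpl12, Rps18, mt-Nd2 and Ptma. Genes of HSC identity were lower for 16 of 16, all at the limit (centred median -1.76 or lower). Core autophagy genes were higher for 7 and lower for 7 of 32, with a median of -0.25 that became 1.98 when centred on expressed genes (percentile 100), and Map1lc3a at 0.54, Map1lc3b at -0.23 and Sqstm1 at -0.76 were not called in the authors' deposited table. Some lists of other cell types had few called members: 3 higher and 2 lower of 15 lymphoid and B cell genes, 1 higher and 2 lower of 11 T and NK cell genes, 1 higher of 6 mast cell and basophil genes and 1 higher of 10 macrophage genes. These included Cd3d and Hdc at 4, Ighm at 3.63, Satb1 at 3.06 and Hmox1 at 2.33 in the authors' deposited table. Megakaryocyte genes were higher for 2 and lower for 6 of 12, and erythroid genes lower for 5 of 15 and higher for none. Multipotent progenitor genes were higher for 5 and lower for 4 of 10. In all, 8199 genes were called, 1044 higher and 7155 lower. In counts adjusted over the list alone, there were 3 higher genes of the ribosomal protein pattern, with the other counts the same. Between c5 and c6, 706 genes were higher in both, where independent lists would share 74.9, with the same limit of shared cells.

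Cluster c7 was marked by genes of B cells. At the upper limit of 4 in the authors' deposited table of c7 against the other cells were Cd79a and Cd79b, the signalling chains of the B cell receptor, the immunoglobulin genes Ighm and Igkc, the transcription factors Ebf1 and Klf2, and Btg1, Cd37, Ly6d and Vpreb3. Lymphoid and B cell genes were higher for 9 of 15 and lower for none, with a median at the limit, and MHC class II genes for 5 of 8 (median 3.15), with Cd74 and H2-DMb2 at 4 in the authors' deposited table. Genes of HSC identity were lower for 11 of 16 with a median at the limit, and Procr was at -4 in the authors' deposited table. Among the genes at -4 in the authors' deposited table were the interferon-induced membrane genes Ifitm1, Ifitm2 and Ifitm3, Tmem176b, Adgrg1, Zfp36l2, Car2, Lmo2, Cd63 and Ctla2a. Malat1 was 0.94 higher in the authors' deposited table. In all, 1239 genes were called, 204 higher and 1035 lower, and the median of expressed genes was -0.92. In counts adjusted over the list alone, there were 10 higher lymphoid and B cell, 6 higher MHC class II and 13 lower HSC identity genes. Cd79a lies on chromosome 7 from 24897381 to 24902197 (plus strand).

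**Figure D3:**
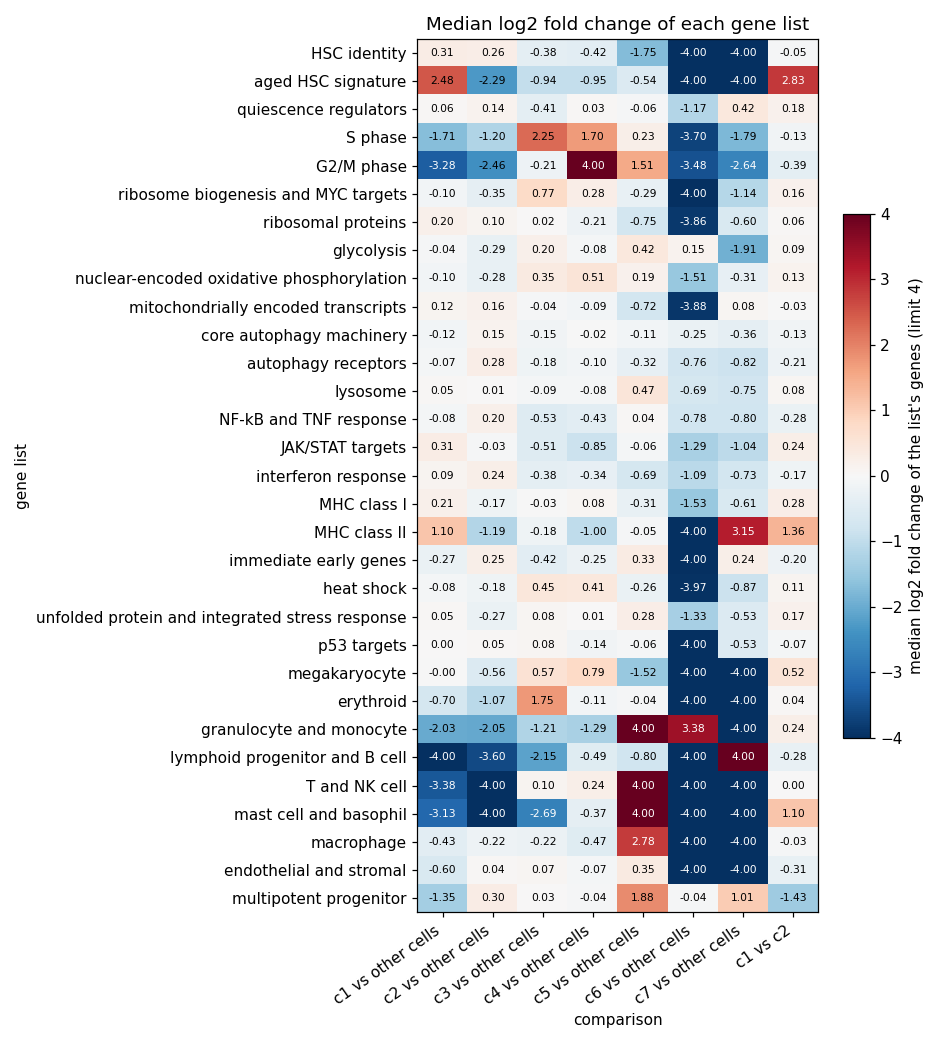
Median log2 fold change of each of the 31 gene lists (vertical axis) in each of the 8 deposited comparisons (horizontal axis), with red for higher and blue for lower values and the limit at 4. The aged HSC signature is at 2.48 in c1 and -2.29 in c2, and most lists are below 0 in c6, where the median of expressed genes was -2.24.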

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

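Leaving out X and Y genes, leaving out genes at the fold change limit and centring the fold changes were tests chosen only after the results were seen. No paired analysis was possible because the deposited tables hold cluster comparisons and no samples, and for the same reason the planned fits of young against old and without each replicate were not run. A minimum absolute log2 fold change of 1 lowered the calls, by its construction, to 2002 in c1, 1631 in c2, 1085 in c3, 1798 in c4, 1947 in c5 and 1402 in c1 against c2. The share of calls that were higher went from 42.6% to 17.8% in c2 and from 69.7% to 57.8% in c4. In c7 an adjusted p of 0.01 left 699 genes. Without genes at the limit, 4893 were left in c6 and 672 in c7, since fewer genes entered. With genes at or above the median expression and a fold change of at least 1, c1 against c2 had 369 called genes in the direct table and 753 by the difference of the c1 and c2 tables, in which the cells outside each cluster include the other cluster. The counts without X and Y genes, at or above the median expression and with the adjustment recomputed stayed within 1.5 times in all 8 comparisons. Centring on the median of expressed genes turned the sign of some list medians that stood apart. In c6 these were oxidative phosphorylation (0.73), core autophagy (1.98), autophagy receptors (1.48), lysosome (1.55), NF-kB (1.46), interferon (1.15) and multipotent progenitor (2.20). In c7 they were oxidative phosphorylation (0.60) and core autophagy (0.55), and in c3 ribosomal proteins (-0.054). List means in place of medians ended the standing apart of 30 list and table pairs and made 9 new ones, unmatched random lists 53 and 10, and expressed members alone 9 and 12. At an adjusted p of 0.01, 93 of the named gene values were no longer called and 900 still were. The depth per cell and the number of cells are unknown, so what they limit was not assessed.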

Other observations

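The tests on a single sex in each cluster, on autosomal genes and on rare transcripts in c6 were chosen only after the results were seen. Of the granulocyte and monocyte list, 5 genes were higher and 5 lower in c1 than in c2. The authors' deposited table of c1 against c2 gave 2.07 for Ctsg, 1.98 for Elane, 1.83 for Mpo and 1.30 for Prtn3, which encode enzymes of neutrophil granules. Cebpa, a transcription factor of the myeloid line, was at -2.03 and Irf8, another, at -0.44 in the authors' deposited table, while Cebpe at -0.59 was not called. Against all other cells, Mpo was at -2.03 in c1 and -3.88 in c2 in the authors' deposited table. Prtn3, Irf8 and Cebpe were named after their values were seen, and no test set these genes against each other. The list holds no transcription factors besides Cebpa, Cebpe and Irf8. The other members called lower, not named here, thus encode other proteins, and lower values were not particular to transcription factors.

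Clusters with genes of mature lineages made up a small part of the cells behind the tables. By the estimate from the tables, c5, c6 and c7 together held 3.12% of the cells (bootstrap interval over genes 3.07 to 3.15). That interval covers the choice of genes alone and not an error of the method. Between c5 and c7, 87 genes were higher in both, where independent lists would share 14.6, though both tables share the remaining cells.

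Xist was lower in c1 than in c2, at the limit of the fold change. Of the 1377 called genes with a fold change of at least 1 and a known chromosome, 96.7% were autosomal, against 96.7% of all genes. Genes on X and Y were thus a small part of the difference. The bound for the opposite outcome could not have been met, since only 629 X and 9 Y genes were present. Nor does the count say whether the autosomal differences go with sex. Clusters of a single sex each would leave the female one without Y-linked transcripts, but the highest fold change among the 4 Y-linked genes was 1.03. Their median of 0.71 lay between the bounds written before those genes were looked at, so by itself it did not settle a difference of sex. Beside these higher Y-linked genes, the X-linked genes known to escape inactivation were lower in c1, from -0.37 to -0.51, and Tsix was at -3.47. Without knowledge of strand the reads of Tsix cannot be told apart from those of Xist, so Tsix adds no separate evidence. Each of these differences has the direction that a smaller share of female cells in c1 would give. That mix could not be tested, since no table ties cells to samples. Sex, the age of the mice and the state of the cells thus cannot be told apart in the differences between c1 and c2.

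Most genes were lower in c6. Rare transcripts missed in a small cluster would leave abundant genes near 0, but the 2006 genes of the highest expression bin had a median of -2.05. Their interquartile range of 2.74 passed the bound set beforehand against a single scaling factor, but that bound was wrong, since differences between cell types widen the range with or without a shift. Mean expression summed to 10000 over genes, as scaling of each cell to a fixed total would give. If the fold changes are ratios of mean values scaled in that way, lower values for 87.1% of these 2006 genes had to be offset by higher values of other genes. Some of the decreases would then reflect a shift set by abundant genes, and its size was not assessed. How the fold changes were computed is not given in the sources used here, and for means of log values no such offset is required. No biological explanation was tested, and the counts per cell that would show a low RNA content were not analysed here.

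Autophagy receptor genes were lower in c1 than in c2. Their median lay at percentile 3.67 of random lists with the same expression, inside the bound of 2.5 set beforehand. By that bound the expression level of the genes was not set aside as a source. Most random lists lay higher, however, with a median of -0.055. Of the 12 genes 9 were called lower, against 4423 of all 20062 genes, a share not matched on expression. Among genes at or above the median expression, 5909 were called, of which 36.9% were higher in c1. In c2 against the other cells, the same list lay at percentile 99.8. Those other cells include c1, estimated at 40.4% of all cells, so that value is no separate evidence. A difference in depth would lower weakly expressed genes most, but only genes at or above the median expression were compared. Among these, the lowest expression bin of 5 lay -0.11 from the highest, less than the list median of -0.21, which does not settle it. No biological explanation was tested for this list, since the tables carry neither age nor GFP-LC3 level.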
